A study of Mus musculus with 6 samples.

How the data were processed

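Gene expression was measured in the paraventricular nucleus of the hypothalamus (PVH), a group of neurons that controls feeding, stress hormones and autonomic output. The mice were male, on a C57BL/6 background and 6 weeks old. In 1 genotype the DNA methyltransferase gene Dnmt3a was deleted with Sim1-Cre, a recombinase driver active in most PVH neurons, and the other genotype was wild type (WT). Per the labels and the series' design text, each genotype had 3 independent pools, each with RNA from 5 animals, and each pool was hybridised to 1 array of an Illumina mouse whole-genome BeadChip. All 6 arrays lay on 1 chip, with the WT pools on the first 3 positions and the deletion pools on the last 3, so position and genotype cannot be told apart. The number of arrays, 3 per genotype, limits the precision of all values.

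The authors deposited 3 tables. The first holds a signal intensity and a detection p-value per probe and array for 45281 probes, named non-normalized by the authors. Its 6 deposited intensity columns nevertheless hold the same sorted values (the largest difference between arrays at any rank was 0.3), with a lowest value of 97.7, a median of 122.6 and a highest of 42836.7. The signals had therefore been quantile normalised across arrays, without background subtraction, before deposit. The second table holds deposited log2 values, which equal log2 of these signals minus each probe's median over the 6 arrays, with a largest difference of 1.8e-06. The column medians of that table ran from -0.00317 to 0.004, and neither scale, centring nor direction stayed unknown. The third is the authors' deposited table of their own comparison, with a log2 fold change, a p-value and a Present, Marginal or Absent call per array for 1302 probes. Per the file headers, it holds an unpaired t-test in which no multiple testing correction was applied, kept at a p-value under 0.05, on probes filtered by Present or Marginal calls. The software used by the authors was GeneSpring GX, per the labels' series design text; its version and the genome build are not given in the sources used here. In the values, Present calls went up to a detection p of 0.2 and Marginal calls up to 0.4, and 28684 probes were Present or Marginal on all 3 arrays of at least 1 genotype. All 1302 probes lay among these 28684. An equal-variance test on the log2 values, with Absent values left blank, gave 1039 of the 1302 deposited p-values within 1e-04.

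Gene names came only from the authors' deposited table, so names exist only for probes that its authors had selected at p under 0.05 on these same arrays. Symbols were updated through the RefSeq annotation of mouse assembly GRCm38.p6 by current symbol, Entrez number, unversioned accession or a unique synonym. Of the 1302 probes 1063 matched and 239 kept the name in the file, giving 1266 distinct names. Names that were only a clone, predicted-gene or accession label (281 probes) were counted but not named. Every other probe is unnamed here, which says nothing of the gene it measures. The direction of a named gene is for this reason not independent of the authors' selection, and each test across named genes describes that selection.

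The main analysis was fixed in advance. Signals were background corrected and normalised with neqc of limma 3.58.1 in R 4.3.3 (normexp by detection p, quantile, offset 16). The background step thus ran on signals that had already been quantile normalised, not on raw ones. Probes with a detection p under 0.01 on at least 3 arrays were kept, which left 16284 probes, 656 of them named (631 genes). Deletion and WT were compared with lmFit and eBayes, all 6 arrays and no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All log2 differences are deletion minus WT, with the standard error (SE) of the limma fit. A probe with a detection p of 0.01 or more on all 3 arrays of a genotype was taken as not above background there. It has only a bound, written "at least", which sets the brighter genotype's mean against the mean of, per array, the higher of the lowest value among detected probes and the probe's own, on the normalised log2 scale. Where a gene had several probes, the one with the highest mean represented it. An n of 3 refers to pools, and an exact permutation test of 3 against 3 could not fall below a two-sided p of 0.1.

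The genes named in the text followed a rule fixed at the same time. It took Dnmt3a, Sim1, Th, Gal, Oxt, Avp, Crh, Trh, Sst and Mc4r where measured, then the 8 largest rises and 8 largest falls among probes with adjusted p under 0.05 whose deletion arrays all lay beyond all WT arrays. Free places went to the smallest unadjusted p among non-overlapping probes in that direction, said to have missed the threshold. Of the lower genes that the rule takes, 1 is not reported here. Up to 4 members of each described gene list with the smallest p were added. In all, 35 gene lists of pathways, cell types and neighbouring regions (585 genes) had been fixed for camera and fry. These tests need names for all measured genes and were not run, nor was an adjustment over each list alone, since 50 of the 585 genes had a name. In their place, the members found in the authors' deposited table were counted by direction, and lists with at least 3 of them were compared with the rest of the table by a two-sided Fisher's exact test, adjusted over the 6 lists. With 3 named members that exact test cannot fall below p = 0.12, so it cannot pass for the 5 lists of that size.

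The fit was tested on simulated data with 200 of 16284 probes changed, 5 times, for the deletion against WT comparison. Without any other structure it recovered 32.8% of changes of 0.5 on the log2 scale, 84.8% of changes of 1 and 98.4% of changes of 2. With the differences among the arrays within genotypes put in as these arrays show them, it recovered 0.8%, 46.7% and 89.6%, so most changes near 0.5 could not be called. Alternatives fixed before the data were examined covered the background correction, the normalisation, the authors' values, the filter, the variance model, array weights, the replicate number as a block, an ordinary t-test (the methods' t-test), each array left out and another probe per gene. Alternatives chosen after seeing the data were the authors' flag filter, a principal component as a covariate and the fit without both WT 3 and deletion 3. Figures were drawn with matplotlib 3.10.9.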

Results

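The arrays compared the PVH of WT mice with that of mice whose Dnmt3a had been deleted by Sim1-Cre, to find which transcripts differ when PVH neurons lack this methyltransferase. There were 3 pools per genotype, each from 5 male mice aged 6 weeks. Between 15640 and 16482 of the 45281 probes had a detection p under 0.01 on an array, and 16284 probes entered the comparison. Dnmt3a, Sim1, Oxt, Avp, Crh, Trh and Mc4r were not named here, so neither the deleted gene nor the driver gene has a value that checks the genotype labels.

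Prph, which encodes the neuronal intermediate filament peripherin, was the single gene whose expression rose past the threshold in the deletion pools. Its log2 intensity was 6.77 ± 0.21 (SD, n = 3 pools) in WT and 8.81 ± 0.17 (SD, n = 3 pools) in the deletion, a 4.13-fold rise. The log2 difference was 2.05 with an SE of 0.15 and an adjusted p of 0.0494 by limma. A second Prph probe was not above background in any WT pool, was at least 1.72-fold higher in the deletion and missed the threshold (adjusted p = 0.0933 by limma). Without background correction the differences on the 2 probes were 1.33 and 0.36. Th, which encodes tyrosine hydroxylase, the rate-limiting enzyme of catecholamine synthesis, lay on chromosome 7 in the authors' deposited table, with the build not given in the sources used here. Its log2 intensity was 7.98 ± 0.13 (SD, n = 3 pools) in WT and 9.71 ± 0.23 (SD, n = 3 pools) in the deletion. The difference of 1.73 (SE 0.14, 3.31-fold) lay just outside the threshold at an adjusted p of 0.055 by limma. Bag3, a co-chaperone of Hsp70 in selective autophagy, had a difference of 1.51 (SE 0.13, 2.85-fold) and the same adjusted p of 0.055. For Th and Bag3 the differences without background correction were 1.37 and 1.32.

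The other places for higher genes went to genes that missed the threshold, although all 3 deletion pools lay above all 3 WT pools in each. Ush1c, a scaffold protein of hair-cell stereocilia, had a log2 difference of 1.19 (SE 0.13). Mfng, a glycosyltransferase that modifies Notch receptors, had 1.08 (SE 0.17). The aminopeptidase-like gene Npepl1 had 0.87 (SE 0.11), and its second probe gave 0.63 (SE 0.09). The beta-defensin family member Defb18 and the secreted ligand gene Wnt10a were not above background in any WT pool, and were at least 2.22-fold and at least 1.73-fold higher in the deletion. Adjusted p-values of these 5 genes ran from 0.134 for Wnt10a to 0.463 for Mfng by limma. Without background correction the log2 differences were 0.64 for Defb18, 0.54 for Mfng, 0.50 for Ush1c and 0.32 for Wnt10a, so the size of the change in dim probes depended on that step.

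No probe was lower in the deletion at an adjusted p under 0.05 by limma, and 239 probes were lower at an unadjusted p under 0.05. The methods' t-test gave 0 probes in either direction after adjustment. Among named genes lower without overlap on their brightest probe, the 8 with the smallest p all missed the threshold. Tac1, the precursor of the neuropeptide substance P and a fixed marker of the preoptic area and bed nucleus, had a log2 difference of -0.57 (SE 0.10). Nms, the gene of the neuropeptide neuromedin S, and Spink8, of a family of serine protease inhibitors, were not above background in any deletion pool, and were at least 1.61-fold and at least 1.22-fold higher in WT. The olfactory marker protein gene Omp differed by -0.57 (SE 0.11). Nrn1l differed by -0.68 (SE 0.13), Shisal2b by -0.50 (SE 0.09) and Magohb of the exon junction complex, above background in 1 of 3 deletion pools, by -0.59 (SE 0.10). Their adjusted p-values ran from 0.155 for Nms to 0.894 for Nrn1l and Omp by limma. Without background correction the dim probes of Nms, Spink8, Magohb, Nrn1l and Shisal2b differed by -0.27, -0.28, -0.17, -0.33 and -0.16.

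**Figure D1:**
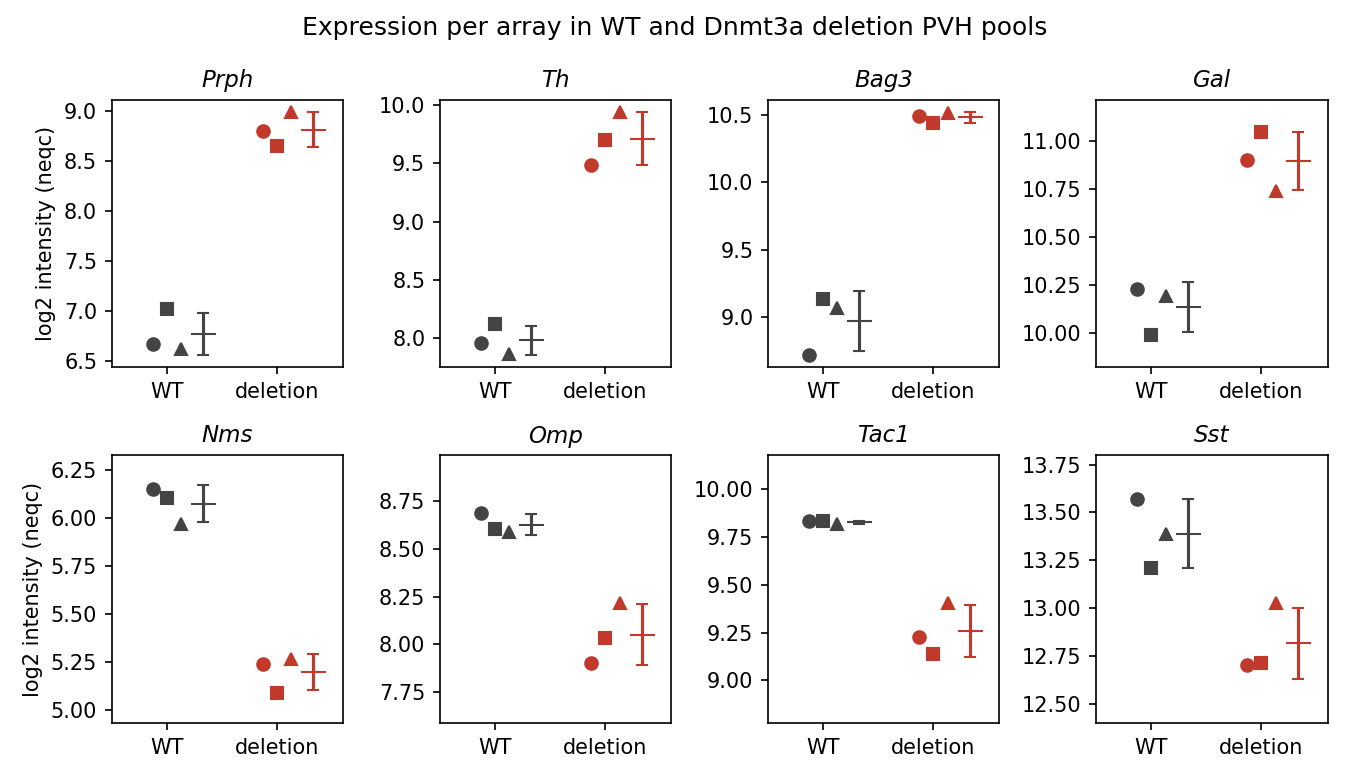
Log2 intensity (vertical axis) of 8 genes in the WT and deletion pools. Each point is 1 array (circle, square and triangle for pools 1, 2 and 3, which were not taken as paired). The bar beside them is the mean with the SD of 3 arrays. Deletion pools lie above all WT pools for Prph, Th, Bag3 and Gal and below them for Nms, Omp, Tac1 and Sst, and Prph alone passed the adjusted threshold; Nms was not above background in the deletion pools.

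Of the 28 PVH neuropeptide and hormone genes fixed in advance, 8 were named in the authors' deposited table, 6 lower and 2 higher (Fisher's exact p = 0.173 against the rest of the table, adjusted p = 0.374 over 6 lists). Since the table was selected on these pools, the counts are not independent evidence of direction. The lower ones were Sst, Tac1, Adcyap1, Cartpt, Nts and Nppc, and the higher ones Gal and Bdnf. Nts, Nppc and Bdnf did not pass the detection filter here, which left 4 lower and 1 higher. Sst, the somatostatin gene, had a log2 difference of -0.57 (SE 0.14, adjusted p = 1 by limma), from 13.39 ± 0.18 to 12.82 ± 0.18 (SD, n = 3 pools each). Adcyap1, which encodes the peptide PACAP, had -0.45 (SE 0.10). Gal, the galanin gene, had 0.76 (SE 0.12, 1.70-fold) with an adjusted p of 0.463 by limma, from 10.13 ± 0.13 to 10.90 ± 0.15 (SD, n = 3 pools each). Of 22 genes of catecholamine synthesis, transport and receptors, 2 were named, Th and the adrenergic receptor gene Adrb1 (log2 difference 0.22, SE 0.09), which missed the threshold. Among 29 energy balance receptors 3 were named, with differences of 0.74 (SE 0.16) for the calcitonin receptor gene Calcr, -0.56 (SE 0.15) for the vasopressin receptor gene Avpr1a and -0.42 (SE 0.14) for the thyrotropin-releasing hormone receptor gene Trhr. None of the 3 passed the threshold (Fisher's exact p = 0.62 for the list, where 3 members cannot give less than 0.12). Without background correction the differences were 0.06 for Adrb1, 0.41 for Calcr, -0.32 for Avpr1a and -0.16 for Trhr.

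The other lists had few named members, none of which passed the threshold. All 3 named imprinted genes were higher in the authors' deposited table (Fisher's exact p = 0.25, adjusted p = 0.374), namely Dlk1 at a log2 difference of 0.57 (SE 0.14), Calcr as above and Meg3 at 0.17 (SE 0.09). The immediate early genes Jun, Fosl2 and Ccn1 were likewise all higher in that table (Fisher's exact p = 0.25), with 0.44 (SE 0.14) for Jun, the 1 detected here. All 3 named oxidative phosphorylation genes were higher by small amounts (Fisher's exact p = 0.25), 0.20 (SE 0.09) for Cox5b, 0.10 (SE 0.08) for Ndufa2 and 0.10 (SE 0.09) for Cox6a1. Of the DNA methylation and demethylation genes, 1 of 20 was named, Tet2, a methylcytosine dioxygenase, above background in 1 of 3 deletion pools, at -0.44 (SE 0.14), or -0.12 without background correction. In the list of PVH developmental transcription factors, Fezf2, also a fixed marker of the ventromedial hypothalamus, had 0.54 (SE 0.10) and Bhlhe40 had -0.10 (SE 0.08).

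Markers of neighbouring regions and other cell types were named too rarely to show a shift of any tissue. For the thalamus, 3 of 12 markers were named, with log2 differences of 0.63 (SE 0.13) for the vesicular glutamate transporter gene Slc17a7, 0.59 (SE 0.12) for Tnnt1 and -0.27 (SE 0.10) for Calb2 (Fisher's exact p = 1). For the suprachiasmatic nucleus, Nms had the bound given above and Rgs16 had 0.39 (SE 0.13). Single markers were named of the ventromedial hypothalamus (Fezf2, given above), the preoptic area and bed nucleus (Tac1, given above), the arcuate nucleus (Tac2, above background in 1 WT and 2 deletion pools, 0.34, SE 0.12) and the lateral hypothalamus (Meis2, 0.23, SE 0.09). The astrocyte marker Gfap had 0.12 (SE 0.09), the microglial marker C1qa had 0.19 (SE 0.09), the endothelial marker Slco1c1 had -0.38 (SE 0.11) and the choroid plexus marker Clic6 had -0.29 (SE 0.11). Without background correction the differences were 0.10 for Tac2, 0.26 for Slc17a7, 0.37 for Tnnt1, 0.07 for C1qa and -0.17 for Clic6. Of the fixed lists, 5 had no named gene, among them those of oligodendrocytes and ependyma. Another was the list of endoplasmic reticulum stress and heat shock, with 0 of 23 genes named.

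The arrays differed among themselves more along another line than between genotypes. Correlations across the 16284 probes ran from 0.957 between WT 3 and deletion 3 to 0.994 between WT 1 and WT 2, and WT 3 and deletion 1 reached 0.992. WT 1, WT 2 and deletion 3 lay on one side of the first principal component of all probes and WT 3, deletion 1 and deletion 2 on the other. Its mean was -0.0359 in WT and 0.0359 in the deletion in units of its SD over arrays. The first component of the variation within genotypes parted the arrays in the same way and took 76.2% of that variation. For the genes above, all 6 arrays were used whatever their place on this component.

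**Figure D2:**
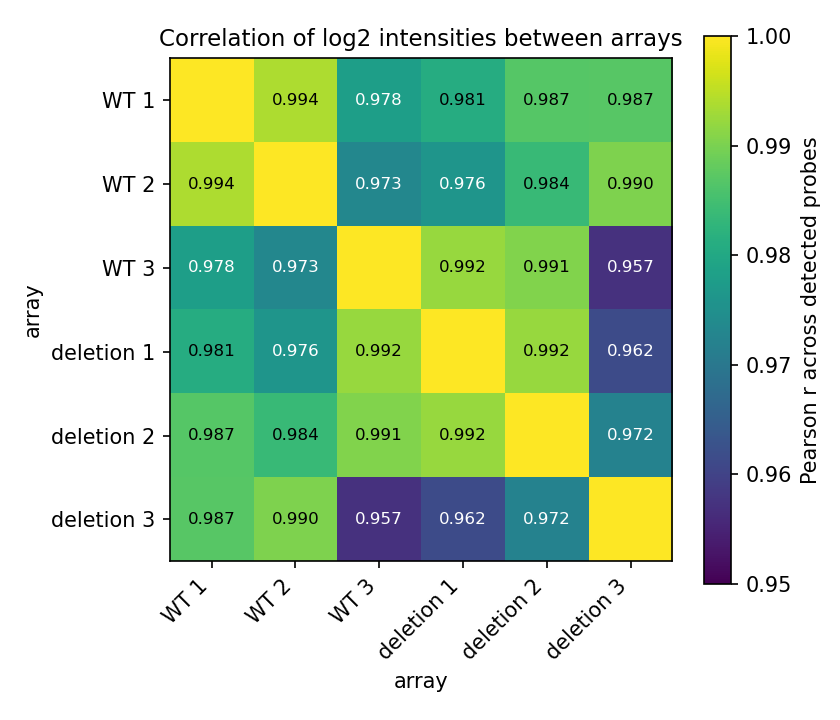
Pearson r between the log2 intensities of each pair of arrays across the 16284 detected probes; rows and columns are arrays, and the colour gives r from 0.95 to 1. The highest r within a genotype was 0.994 and the lowest r, 0.957, joined WT 3 and deletion 3.

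Over all 16284 probes, 477 had an unadjusted p under 0.05 by limma, 238 higher and 239 lower in the deletion, where uniform p-values would give 814. Those 477 are 2.93% of probes, and simulated data with these arrays' differences within genotypes and no genotype change gave 1.73%. With 1 array left out the count ran from 308 without WT 1 to 921 without deletion 3. Array weights gave 2313. The 3 deletion arrays lay beyond all 3 WT arrays for 7.65% of probes, and chance gives 10%. In the authors' deposited table, 657 probes were higher and 645 lower at an uncorrected p under 0.05, which is 4.54% of the 28684 probes that pass its flag filter. Log2 fold changes in that table ran from -0.57 to 1.41, with a median size of 0.10, and 3 of the 1302 probes reached a size of 1. Of its genes with several distinct probes there, the 2 brightest had the same direction in 29 of 35 genes (82.9%, exact binomial interval 66.3% to 93.4%, p = 0.000117), which bears on the RNA of these pools and not on genotype. Both probes had to pass the authors' selection, so genes with an unchanged second probe are left out and the share does not hold for all genes. The call of Prph was lost when any 1 of the 6 arrays was left out, without a filter on dim probes, with the authors' flag filter and by the methods' t-test. On the authors' log2 values, Prph, Th and Bag3 all passed the threshold by limma.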

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

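The authors' flag filter, both principal component covariates and the fit without both WT 3 and deletion 3 were chosen after seeing the data. With 1 probe higher and 0 lower as the main counts, higher probes numbered 3 without background correction, after a 75th percentile shift, on the authors' log2 values, with detection on all 6 arrays and with an intensity trend and robust variance (Prph, Th and Bag3 each time). They numbered 5 with array weights, with 1 lower probe (Nms). They numbered 0 without a filter on dim probes, with the authors' flag filter and by the methods' t-test, which had 654 probes at an unadjusted p under 0.05. The first pair of these tested more probes and also refitted the variance model on them, and the cause was not tested for any of these. Leaving out 1 array at a time gave 0 to 1 higher and 0 lower probes, the 1 being Defb18 without deletion 2, with fewer arrays in each fit. With the first residual component as a covariate 9 were higher and 1 lower, and with the first component of all probes likewise 9 and 1. Without both WT 3 and deletion 3 there were 608 higher and 118 lower. That fit sets WT 1 and WT 2 against deletion 1 and deletion 2, which also lie apart on the first component, and 641 of its 726 probes were among those that component's split calls. Median scaling gave 1 and 0.

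With the replicate number as a block, 0 probes were higher and 0 lower. Same-numbered arrays deviated from their genotype means with correlations of -0.452, -0.472 and -0.771. The rule fixed in advance asked for more than 0.1 in every pair, so the pools were not taken as paired. For each number the WT and deletion arrays lay on opposite sides of the first component. That pulls these correlations down, so they cannot exclude shared litters or days. The block also removes degrees of freedom, and why it gave 0 probes was not tested.

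All 48 named genes had their main direction in each of 1049 values under alternatives, which their selection on these arrays favours. Of these, 47 passed the threshold where the main value had not, and 10 of Prph lost it. Most of the 47 came from fits chosen after seeing the data, with a component as covariate or without both WT 3 and deletion 3. Gal, Sst, Tac1, Omp, Spink8, Magohb, Nrn1l, Mfng, Jun and Slc17a7 passed only in the fit without both, which is mixed with the array split. All 100 list medians under alternatives had the main sign. Among the genes above, Th ran from 1.37 to 1.84 and Prph from 1.33 to 2.17, both lowest without background correction. The other probe per gene was the one with the smallest p, for Prph the main probe itself. The range therefore leaves out the second Prph probe, which gave smaller values. Adjusted p of Prph ran from 0.000465 to 1. Values of dim probes depend on signal over background. Camera and fry, the list counts by them and the Dnmt3a value were not run or could not be given. The authors' deposited table holds only probes selected at an uncorrected t-test p under 0.05, so it gave no probe counts after adjustment.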

Other observations

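All tests in this part were chosen after the results were seen. So were the genes of the next paragraph, all of which missed the threshold.

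Hspb8, a small heat shock protein that acts in a complex with Bag3, had log2 differences of 0.82 (SE 0.13) and 0.88 (SE 0.13) on its 2 probes, with all deletion pools above all WT pools. Fxyd5, a modulator of the sodium pump, was higher on 3 probes, by 0.92 (SE 0.17), 0.47 (SE 0.11) and 0.63 (SE 0.14). Cartpt, the precursor of the feeding-related CART peptides, was lower on 2 probes, by -0.59 (SE 0.09) and -0.49 (SE 0.13). Pkib, an inhibitor of protein kinase A, was lower on 2 probes, by -0.52 (SE 0.13) and -0.59 (SE 0.14). The second Dlk1 probe gave 0.68 (SE 0.16) and the second Fezf2 probe 0.59 (SE 0.11). Other neuronal genes were Sncg at 0.73 (SE 0.16), Pvalb at 0.70 (SE 0.18) and the photoreceptor cadherin gene Cdhr1 at -0.71 (SE 0.15). The neuropeptide gene Grp was not above background in any deletion pool and was at least 1.51-fold higher in WT. Without background correction dim probes gave smaller values, -0.22 for Grp, -0.39 for Cdhr1, 0.55, 0.23 and 0.25 for the 3 Fxyd5 probes in the order above, 0.54 for the second Hspb8 probe and -0.30 for the second Pkib probe. Among detected probes, the 2 brightest of a gene had the same direction in 23 of 24 genes of the authors' deposited table, Cldn10 being the exception. Here too both probes had passed the authors' selection.

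The labelled genotypes gave 1 probe at an adjusted p under 0.05, and 2 of the 10 splits of the 6 arrays, the labelled one included, gave at least as many. The highest other split gave 1435, which points to a structure of the arrays, and 10 splits are too few for a share under 0.05. A candidate explanation for the low count is the spread that this structure adds. With the first residual component as a covariate, 7.12% of probes had an unadjusted p under 0.05, against 2.93% without it, 1.73% on simulated data with the structure and no change, and 5.52% for the same covariate on simulated data with neither. In simulated data with the structure put in, the comparison of deletion with WT over 16284 probes recovered 46.7% of log2 changes of 1, and 77.3% with the covariate. The 10 probes called with it belonged to Prph, Th, Bag3, Wnt10a, Ush1c, Npepl1, Defb18 and Hspb8, which were higher, and Nms, which was lower.

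The split of WT 1, WT 2 and deletion 3 from WT 3, deletion 1 and deletion 2 reached log2 differences of 5.41, and 946 of its 1435 probes were higher in the second set. The probe with that difference read 5.51, 5.22 and 5.37 in the first set and 11.86, 10.89 and 9.57 in the second. In WT 2 and deletion 3 it lay below the lowest detected values there, 5.346 and 5.401. The size of 5.41 thus rests on readings near background. A bright probe went the other way, with 13.22, 13.55 and 13.88 in the first set and 8.78, 10.36 and 11.41 in the second. Technical differences between arrays were not tested, as the deposited signals already shared 1 distribution. An exchange of the labels of WT 3 and deletion 3 stays open. The labelled split had 7 probes at an unadjusted p under 1e-04 and the highest of the 8 remaining splits had 1, but so few splits cannot give that rank a share under 0.05, and Dnmt3a has no named probe. A different tissue make-up of the dissected pools also stays open. So does position on the chip, where the second set lay on the middle positions and the first set on the outer ones. These explanations cannot be told apart here. Of the fixed markers 0 were named among these probes, but only 1 of the 1435 probes had a name. Names exist only for probes selected on the genotype comparison, so that count decides nothing.

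The 16 genes that the rule took as higher or lower, Prph by its size and the others by their p, were taken only where the genotypes did not overlap. A probe that follows the array split overlaps between genotypes and could not be taken. The list therefore cannot test the array structure as a source of these differences. The first component of all probes is balanced over genotype, with means that differ by 0.0718 SD over arrays. Its SDs were 0.992 within WT and 1.23 within the deletion. That balance describes the arrays and not these genes. Hybridisation peculiar to a probe stays open, as 2 of these genes, Prph and Npepl1, had a second probe in the authors' deposited table, both in the same direction. So does tissue make-up, with 2 of the 3 named thalamus markers higher in the deletion and 9 of the 12 unnamed, as does position on the chip, which follows genotype. The exchange of the labels of WT 3 and deletion 3 also stays open, and the labelled groups would then mix the genotypes. The deletion itself is the biological explanation that the design names, and it cannot be told apart from these here.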
